A study of Torulaspora delbrueckii with 9 samples.

How the data were processed

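Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out by the authors on cultures of the budding yeast Torulaspora delbrueckii. The labels name 9 samples. 6 of them are immunoprecipitates of a tagged subunit of the origin recognition complex (ORC), with 2 libraries each for Orc1 carrying a MYC tag and for Orc2 and Orc4 carrying a V5 tag. The other samples are 2 genomic input libraries and 1 mock immunoprecipitate from an untagged strain. Cells were cross-linked with formaldehyde and chromatin was sonicated, per the labels' protocols. The series' design text calls the 2 libraries of a subunit technical replicates, while the sample labels give them different strain numbers.

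The submitters' processing notes name cutadapt 2.10, Bowtie2 2.3.4.1 and MACS2 2.2.7.1. Their settings and the genome build are not given in the sources used here. The data used were 6 deposited peak lists, 1 per immunoprecipitate, so that peaks had been called per library and not on pooled libraries. Reads and signal tracks were not used here, and the input and mock libraries entered only through the peak calls. Peak names in the Orc1 lists name a genomic input as the control, and those in the Orc2 and Orc4 lists name the mock immunoprecipitate. The strain number of the control in the peak names differs from that in the labels, and both were taken to be the same untagged strain. The subunit, the epitope tag, the antibody and the kind of control were therefore confounded between Orc1 and the other subunits. Peak names of the Orc1 lists also hold the words SIR and Kos3V5, which the labels do not explain, so a difference in strain genotype beyond the tag cannot be ruled out in these comparisons. The peak names of all 6 lists also hold the word subsample, which the labels do not explain.

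Each peak has a start, an end, a summit, a fold enrichment (the ratio of the immunoprecipitate to the control at the summit) and −log10 p and −log10 q values, all as deposited by the authors. The deposited score column, an integer scaled from the −log10 q-value, was not analysed. Levels of fold enrichment were tested within a list, and differences between lists were tested only for how they varied between regions near the ends and in the interior. Values of several lists given side by side are relative to different controls. The lists hold no read counts, so the depth per library is unknown and no counting interval can be given for a peak. Precision was judged from the agreement of the 2 lists of a subunit. Intervals given below for shares of regions are exact Clopper-Pearson 95% intervals and cover counting error over regions only. P-values over regions measure only these lists, since regions are not replicates, and p-values over libraries measure a spread between libraries that may be technical.

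Sequence names in the lists are those of the 8 chromosomes of assembly ASM24337v1. This was checked by placing the summits of each sequence on the genes of every chromosome that could hold them. The chromosome of the same number gave the highest share of summits between genes for 8 of 8 sequences, from 81.8% to 100%, against a median of 19.6% for other chromosomes. The gene table of ASM24337v1 holds 5174 genes, of which 4970 are protein-coding, 193 are tRNA genes and 11 are rRNA genes. It has symbols other than locus names for 4126 of them. Gene symbols were used as the table gives them. The end of a chromosome was taken as the last position of a gene or a peak, for a total of 9221 kb. Positions are 1-based.

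Peaks of the 6 lists that overlapped by at least 1 bp were merged into regions. A region was called shared if it had a peak in both lists of all 3 subunits. It was called Orc1-only with a peak in both Orc1 lists and in none of the 4 other lists, and Orc2/Orc4-only with a peak in those 4 lists and in no Orc1 list. The fold enrichment of a region in a list is that of its peak with the highest −log10 q, its width there is the summed width of its peaks, and its summit is the mean over lists. Overlaps were compared with 10000 circular shifts of a list along each chromosome, one-sided for overlap between lists and two-sided for genes, summits between genes and chromosome ends, and their p-values are called circular-shift permutation p-values. The smallest p-values the shifts can give are 0.0001 and 0.0002. Shares were compared between classes with Fisher's exact test, medians with permutation tests of 100000 resamples, widths with a sign-flip permutation test, and libraries with an exact permutation of the 6 libraries over 15 splits, all two-sided. Adjusted p-values follow Benjamini and Hochberg.

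The 11 gene lists were tRNA genes, rRNA genes, ORC genes, silencing genes, replication genes, glycolysis genes, other genes of high expression, mating-type genes, histone genes, ribosomal protein genes and hexose transporter genes. A region or peak was counted with a list if it lay within 1000 bp of a gene of it. Lists, classes, tests and their alternatives were fixed before the data were examined, as was the rule for naming regions. It takes the 8 regions of each class with the highest minimum fold enrichment over the lists that define it, the region of each class with its centre nearest to a chromosome end, and up to 6 regions within 1000 bp of a mating-type, ORC, silencing or histone gene. Covered lengths, peak widths split by distance to the ends, the comparison of fold enrichment beside tRNA genes, spacing against random positions and gene lists tested per library were added after the lists had been examined. Alternatives covered the overlap rule, the peak threshold, equal numbers of peaks per list, each list left out in turn, and the distances used. Tests of base composition and sequence motifs and of the orientation of neighbouring genes were planned but not run, since no genome sequence or gene strand was used here. Centromeres and long terminal repeats, also planned as lists, are not in the gene table.

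The analysis used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The shift tests and the class assignment were tested on simulated lists. Planted overlap and planted proximity to tRNA genes each gave a p below 0.05 in 20 of 20 runs, and unrelated lists did so in 7 of 220 runs for overlap and 10 of 220 for tRNA genes. Of 150 planted shared regions 148 were recovered, as were 13 of 15 planted Orc1-only and 15 of 15 planted Orc2/Orc4-only regions. Planted regions were put in every list of their class with small shifts, at random positions, and the widest peaks were left out. The simulation therefore says nothing about peaks missed in a list or regions merged by wide peaks.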

Results

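The origin recognition complex is the 6-subunit assembly that marks replication origins in eukaryotes. Its Orc1 subunit is the relative of Sir3, a structural protein of silent chromatin in Saccharomyces. Orc1, Orc2 and Orc4 were mapped by ChIP-seq in Torulaspora delbrueckii, with 2 libraries per subunit, and the comparison asked where Orc1 was detected with the other subunits and where it was detected without them. Orc1 lists held 263 and 300 peaks, Orc2 lists 339 and 342, and Orc4 lists 408 and 248. The peaks covered 265 and 386 kb for Orc1, 216 and 208 kb for Orc2, and 285 and 186 kb for Orc4. Median fold enrichment, the authors' value per peak, ranged from 3.84 in Orc4 library 1 to 10.8 in Orc4 library 2.

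Most places bound by a subunit in 1 library were also listed in the other library. Of the 263 peaks of Orc1 library 1, 256 (97.3%) overlapped a peak of library 2, and 227 of 300 (75.7%) did so in the other direction. For Orc2, 279 of 339 (82.3%) and 274 of 342 (80.1%) overlapped. The Orc4 libraries agreed less evenly, with 232 of 408 peaks of library 1 (56.9%) and 240 of 248 of library 2 (96.8%) in both lists. Shifted lists gave between 15.4 and 18.3 overlapping peaks in these 6 comparisons, and the circular-shift permutation p was 0.0001 in each, the smallest the shifts can give (one-sided). Across the 198 shared regions, Spearman's rho of fold enrichment between the 2 libraries was 0.85 for Orc1, 0.97 for Orc2 and 0.98 for Orc4.

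The 3 subunits were found at largely the same places. Merging gave 542 regions, of which 198 were shared, 17 were Orc1-only and 16 were Orc2/Orc4-only. Of 226 regions in both Orc1 lists, 198 (87.6%) were in all 4 Orc2 and Orc4 lists, and of 217 regions in those 4 lists 91.2% were in both Orc1 lists. The other 311 regions met no class, and 202 regions were in 1 list alone. Peaks in 1 list overlapped those of another subunit far more often than after shifting, for example 208 of 263 peaks of Orc1 library 1 with Orc2 library 1 against 14.9 (circular-shift permutation p = 0.0001, the smallest the shifts can give). All Orc2 and Orc4 lists were called against the same mock library, so their overlap also holds what that library contributes. Fold enrichment at shared regions was correlated for all 15 pairs of lists, across regions, which are not independent replicates. Spearman's rho was 0.94 to 0.96 between Orc2 and Orc4 libraries and 0.63 to 0.71 between Orc1 and the others. Median distances between summits were 15.5 to 18 bp for Orc2 against Orc4 and 42 to 64 bp for pairs with Orc1. Between the 2 libraries of a subunit they were 22 bp for Orc1, 7 bp for Orc2 and 8 bp for Orc4.

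Of the 8 strongest shared regions, 6 lay between genes and over 50 kb from an end, and 2 lay at chromosome ends. The region with the highest minimum fold enrichment spanned positions 1407913 to 1418109 at the right end of chromosome 1, beside TDEL0A08060, with 21.2 and 21.5 in the Orc1 lists and 36.0 to 49.6 in the others. A second region at an end spanned 1081709 to 1086937 on chromosome 5, beside TDEL0E05770, with 14.2 and 13.0 for Orc1. The highest single value, 73.2 in Orc4 library 1, came from chromosome 5 at 930473 to 931771, between CIR1 and the serine biosynthesis gene SER2, where Orc1 gave 12.9 and 16.3. On chromosome 2, regions lay at 871996 to 873103 between NDT80, which encodes a meiotic transcription factor, and KRE33, at 465937 to 468315 between CYT1 and YNG1, and at 1169823 to 1170882 between the tRNA gene TDEL0Btrna12A and MRPL3. Further regions were at 73227 to 75380 on chromosome 3, between the actin gene ACT1 and SND2, and at 124724 to 126703 on chromosome 5, between TRM13 and YPT11. Minimum fold enrichment over the 6 lists was at least 12.7 in these 8 regions.

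Some shared regions lay beside genes of ORC, of silencing and of histones, though none of these lists passed the threshold against shifting (given below). Regions beside ORC5 (chromosome 3, 1092012 to 1093106) and ORC4 (chromosome 8, 92027 to 92958) had minimum fold enrichments of 9.47 and 6.67. Regions also lay beside ABF1, which encodes a general regulatory factor (chromosome 1, 424361 to 425773; minimum 12.2), and within 1000 bp of the silencing gene SIR4 (chromosome 2, 348807 to 350381, between ADK1 and MSC3; minimum 9.87). A region between SOK1 and HHF1, the latter encoding histone H4, spanned 784713 to 786875 on chromosome 4 with 5.17 and 6.22 for Orc1 and 21.3 to 34.4 for the others. Another, between ECM15 and TDEL0D04170 near HTB2, spanned 763485 to 764400 on the same chromosome, with a minimum of 5.81. Weaker peaks near histone genes that met no class were at HTB2 (762328 to 762876, Orc2 library 2 with 2.2 and Orc4 library 1 with 2.27), and in Orc4 library 1 alone over HTA1 (1.93) and within 1000 bp of it in MSC3 (1.71). The shared region with its centre nearest to an end, chromosome 1 from 1 to 1135, had 8.88 and 8.56 in the Orc1 lists, relative to input, and 1.41 to 1.81 in the others, relative to the mock.

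Orc1 was listed without the other subunits at 17 regions. The strongest was the left end of chromosome 2, positions 1 to 17323, with fold enrichments of 15.8 and 17.7, which held TDEL0B00100 and TDEL0B00110. Next came 1192153 to 1197312 on chromosome 4 over FRE4, named for a ferric reductase, and TDEL0D06610 (12.8 and 10.6), and 821558 to 832438 at the right end of chromosome 8 (7.64 and 9.43). Narrower regions were at 507645 to 508001 on chromosome 8 between IRC22 and SGN1 (6.02 and 6.76) and at 1050693 to 1051897 on chromosome 3, with the summit in SLA2 (5.54 and 10.0). The rest of the 8 strongest lay between HAT1 and LOC1 on chromosome 3 (204969 to 205335), PHO80 and RRP6 on chromosome 7 (805455 to 805965), and EFM5 and ERG26 on chromosome 6 (401376 to 401678), with 3.17 to 5.06. The Orc1-only region with its centre nearest to an end was 1271 to 3403 on chromosome 1 (2.02 and 4.48). The count depended on having both lists: it was 44 with Orc1 library 1 alone and 80 with library 2 alone.

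Regions of Orc2 and Orc4 without Orc1 were weak. The strongest of the 16 lay in BPH1 (chromosome 6, 551792 to 552330), with 4.30 to 7.51 over the 4 lists, and between APL1 and SAG1 (chromosome 5, 750849 to 751402), with 3.36 to 5.94. Others were between YEA4 and GIM4 (chromosome 8, 499189 to 499679), beside ATP10 (chromosome 5, 235604 to 235919), in HSP12, which encodes a stress-induced membrane protein (chromosome 3, 142620 to 143313), between IBD2 and RIA1 (chromosome 6, 137943 to 138398), beside the glutamate dehydrogenase gene GDH1 (chromosome 8, 772069 to 772409), and in TRM1 (chromosome 6, 742314 to 743319). Their minimum fold enrichments were 2.36 to 2.91. The member with its centre nearest to an end lay beside ADH6 on chromosome 5 (34068 to 34368; 1.67 to 2.41). Without Orc4 library 2 the count rose to 42, and at −log10 q of at least 10 it was 8.

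Peaks at Orc1-only and Orc2/Orc4-only regions had lower median fold enrichment than shared peaks of the same list. The class definition favours this, since shared regions passed the threshold in all 6 lists. In the Orc1 lists the median fold enrichment was 3.17 at the 17 Orc1-only regions against 7.64 at the 198 shared ones in library 1 (permutation, adjusted p = 6e-05), and 4.48 against 8.44 in library 2 (adjusted p = 0.00109). In the Orc2 and Orc4 lists, medians at the 16 Orc2/Orc4-only regions were 2.40 to 3.68, against 12.6 to 18 at shared regions (permutation, adjusted p = 0.00109 in each of these 4 lists). The p-values were adjusted over the 6 lists. The highest Orc1-only values, 15.8 and 17.7 at the left end of chromosome 2, lay above the upper quartiles of shared peaks, 9.39 and 10.6. On average 21.7% of the peaks of an Orc1 list overlapped no peak of another subunit, against 10.2% for Orc2 and Orc4 lists. The difference of 11.5 percentage points did not exceed the spread between libraries (exact permutation p = 0.267 over 15 splits, of which the smallest possible is 0.0667), and Orc4 library 1 reached 20.6%. It was 5.29 points without Orc4 library 1 and 6.44 points without Orc1 library 2. The comparison is uneven, since Orc2 and Orc4 peaks could overlap each other, and their lists have the same tag and control. Orc1 had no such partner. Between Orc1 library 1 and Orc2 library 1, 79.1% of the Orc1 peaks overlapped, against 66.4% of the Orc2 peaks. With Orc4 library 2 the order was the other way, 78.3% of Orc1 library 1 peaks against 86.7%.

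**Figure D1:**
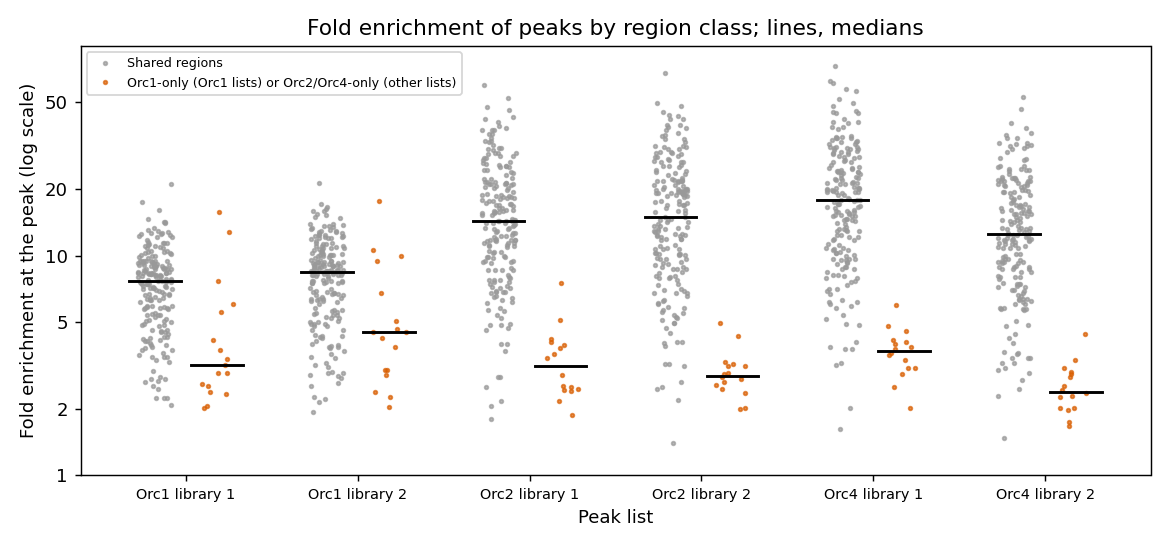
Fold enrichment of peaks (y axis, log scale) in each of the 6 peak lists (x axis), where grey points are the 198 shared regions, orange points are the 17 Orc1-only regions in the Orc1 lists and the 16 Orc2/Orc4-only regions in the other lists, and black lines are medians. The orange medians, 2.40 to 4.48, lie below the grey ones, 7.64 to 18.

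Orc1 covered far more of the chromosome ends than Orc2 or Orc4 did. In the terminal 20 kb of the 16 chromosome ends, Orc1 peaks covered 56.1 kb in library 1 and 145 kb in library 2. Orc2 peaks covered 16 and 15.1 kb there, and Orc4 peaks 21.3 and 16 kb, which made the Orc1 mean 5.87 times that of the others. Median fold enrichment of the peaks there was 3.94 and 2.63 for Orc1, 3.75 and 3.20 for Orc2, and 3.54 and 6.33 for Orc4. Elsewhere the means were 225 kb for Orc1 and 207 kb for Orc2 and Orc4 (exact permutation p = 0.6). Both Orc1 libraries covered more than each of the 4 other lists at 15 of 16 ends, the left end of chromosome 3 being the exception. All ends were measured in the same 6 libraries, so they are not independent, and subunit and control are confounded. The exact permutation p over libraries was 0.0667, the smallest the 15 splits allow. The size rested on Orc1 library 2: without it the ratio was 3.28, and library 2 covered 2.58 times as much as library 1 near the ends against 1.16 times elsewhere.

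**Figure D2:**
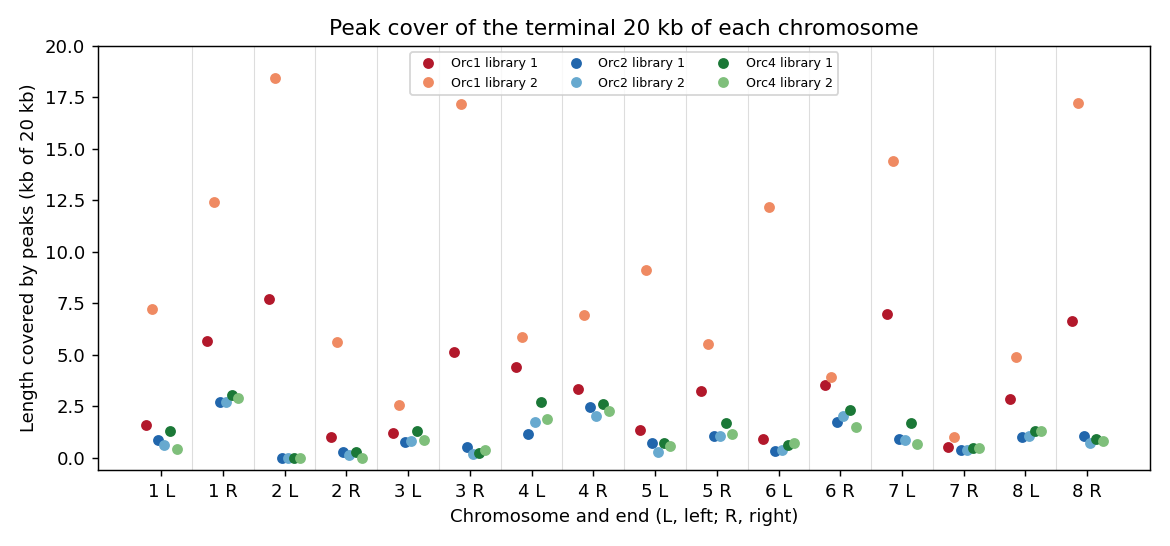
Length covered by peaks (y axis, kb) in the terminal 20 kb of each chromosome end (x axis, chromosome number with L for left and R for right), 1 point per library. Both Orc1 libraries lie above all Orc2 and Orc4 libraries at 15 of 16 ends, and at the left end of chromosome 2 Orc1 covered 7.71 and 18.4 kb and the others 0 kb.

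Orc1 peaks were also wider at shared regions, mainly near the ends. These include peaks counted in the covered length above, so the widths are not separate evidence. At the 16 shared regions within 20 kb of an end, Orc1 peaks were 3.0 times as wide as those of Orc2 and Orc4 (log2 difference 1.59 ± 0.90 SD, n = 16 regions), and wider at 16 of 16 (sign-flip permutation p = 3e-05). The ratio was 2.42 with Orc1 library 1 alone and 3.74 with library 2 alone, and median widths there were 1556 and 3570.5 bp in these lists against 726.5 to 829 bp in the others. At the 172 shared regions over 50 kb from the ends the ratio was 1.06 (log2 difference 0.09 ± 0.37 SD, permutation p = 0.00213). Over all 198 it was 1.18 (log2 difference 0.24 ± 0.60 SD, permutation p = 1e-05, the smallest the resamples can give). Orc1-only peaks were narrower than shared ones, with medians of 460 against 998 bp in library 1 (permutation p = 3e-05) and 461 against 1034 bp in library 2 (permutation p = 5e-05). The class definition favours this as well, since a wide peak is more likely to overlap a peak of another list. For the same reason it favours wide Orc1 peaks at shared regions. Of the 17 Orc1-only regions, 3 were over 2500 bp wide in each library. Peak width depends on depth and on the control, which differed between Orc1 and the others.

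Of the 17 Orc1-only regions, 4 had their centre within 20 kb of an end (23.5%, 95% interval 6.81% to 49.9%), as did 16 of 198 shared regions (8.08%, 4.69% to 12.8%) and 0 of 16 Orc2/Orc4-only regions (up to 20.6%). The first 2 classes lay there more often than after shifting (0.659 expected, circular-shift permutation p = 0.01, and 6.92 expected, p = 0.0002, the smallest the shifts can give). The difference between Orc1-only and shared regions did not pass the threshold (Fisher's exact p = 0.0588). It did with windows of 10 kb (Fisher's exact p = 0.0214) or 30 kb (p = 0.0279). It also did without Orc2 library 2 (Fisher's exact p = 0.0301) or Orc4 library 1 (p = 0.0246). It did not without Orc2 library 1 (Fisher's exact p = 0.0571) or Orc4 library 2 (p = 0.0579), at −log10 q of at least 10 (p = 0.142) or with equal numbers of peaks per list (p = 0.0763). The excess was 58.25 percentage points without Orc1 library 1 and 27.99 without Orc1 library 2. With 1 Orc1 list, neighbouring pieces at 1 end counted as separate regions, such as 5 peaks of library 1 at 821558 to 832438 on chromosome 8. Of 62 regions found in Orc1 library 2 alone, 49 (79.0%) were within 20 kb of an end. Many were neighbouring pieces of the same end, such as those between 12 and 14273 on chromosome 6, so they are not independent.

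The widest Orc1 peaks covered several genes. The widest, 31.6 kb in library 2 at 6.03 fold, ran from 47972 to 79521 on chromosome 5, from TDEL0E00260 into SIR1, the namesake of a silencing gene of Saccharomyces. Library 1 had 6 peaks over 12.3 kb there, with up to 17.6 fold, at 73151 to 76988. The other lists had 4 to 9 peaks that covered 5.27 to 7.39 kb. The strongest of those ran from 74103 to 75233 in Orc2 library 1, over the tRNA gene TDEL0Etrna12V, with fold enrichment of 31.0 there and 23.6 to 33.4 in the other Orc2 and Orc4 lists. On chromosome 3, library 2 had a peak of 13.8 kb from 1269147 to 1282970 over HMLALPHA1 and HMLALPHA2, the annotated mating-type genes, at 12.8 fold. Library 1 covered 6.19 kb there at up to 7.60 fold, and the other lists covered 0.754 to 1.06 kb. Their strongest peak, 5.66 to 9.54 fold, lay left of the mating-type genes, at 1270001 to 1270526 in Orc2 library 1.

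At the left end of chromosome 2 no Orc2 or Orc4 list had a peak within 20 kb. On chromosome 4, 20.8 kb from the right end, the 5.16 kb peak of library 2 over FRE4 and TDEL0D06610 matched 3 peaks over 4.90 kb in library 1, again with none in the other lists. Beside SLA2 on chromosome 3, 241 kb from an end, both Orc1 lists had peaks over TDEL0C05820 and TDEL0C05810 and the other lists had none. All 12 peaks over 5000 bp in Orc1 library 2 overlapped peaks of library 1, which had 3 peaks of that width, and no Orc2 or Orc4 list had any. The wide peaks and the genes under them were singled out after their values had been seen.

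**Figure D3:**
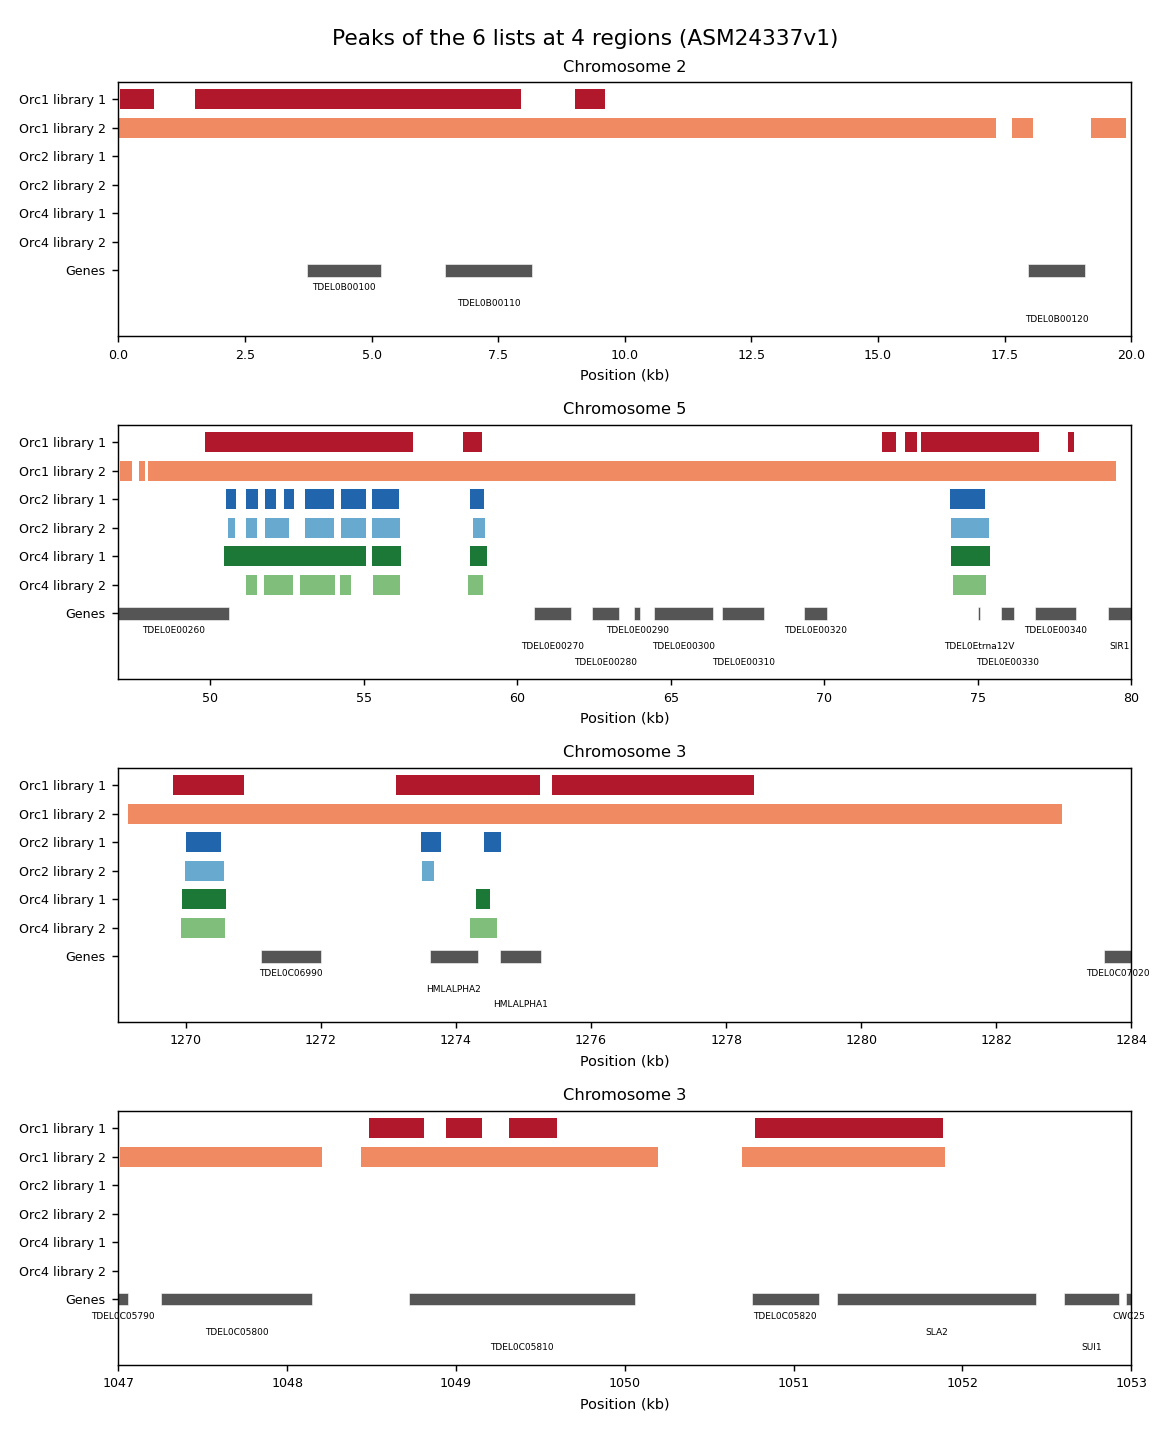
Peaks of the 6 lists (coloured bars, 1 line per library) and annotated genes (grey bars) against position (x axis, kb, ASM24337v1) at the left end of chromosome 2, on chromosome 5 beside SIR1, and on chromosome 3 around HMLALPHA1 and around SLA2. The widest peaks of Orc1 library 2 span 17.3, 31.6 and 13.8 kb in the upper 3 panels, and no Orc2 or Orc4 peak lies in the uppermost and lowest panels.

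Shared regions lay mostly between genes. Of 198 shared regions, 178 had their summit outside annotated genes (89.9%, 95% interval 84.8% to 93.7%), against 20.8% after shifting (circular-shift permutation p = 0.0002, the smallest the shifts can give). The share was 11 of 17 for Orc1-only regions (64.7%, 38.3% to 85.8%) and 10 of 16 for Orc2/Orc4-only regions (62.5%, 35.4% to 84.8%). Both were lower than for shared regions (Fisher's exact p = 0.0086 and 0.00622) and higher than after shifting (p = 0.0006 and 0.0008). The gap between Orc1-only and shared regions depended on the summit. With the centre of the region, 70.7% of shared regions lay outside genes, and the gap was −0.119 percentage points (Fisher's exact p = 1). It also did not pass with reciprocal overlap (Fisher's exact p = 0.711) or at −log10 q of at least 10 (p = 0.205).

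Of the gene lists, tRNA genes stood out. A tRNA gene lay within 1000 bp of 51 of the 198 shared regions, against 13.5 after shifting (circular-shift permutation, adjusted p = 0.0066 over 33 tests of 11 lists in 3 classes, the smallest the shifts can give there). None of the 17 Orc1-only regions and 3 of the 16 Orc2/Orc4-only regions had one (1.40 and 0.797 expected, permutation, adjusted p = 1 and 0.904). Shifted summits lay mostly inside genes, so the shifts cannot separate the excess beside tRNA genes from the placement of shared regions between genes. Fold enrichment at the 51 shared regions beside tRNA genes did not differ past the threshold from the other 147 in any list. The median was higher beside tRNA genes in 5 lists, by 0.175 in Orc1 library 1 and by 2.19 to 3.34 in the Orc2 and Orc4 lists, and lower in Orc1 library 2, with 8.26 against 8.48 (permutation, adjusted p from 0.448 to 0.79 over the 6 lists). No other list passed in any class with all 6 lists of peaks. Without Orc4 library 2, glycolysis genes passed for Orc2/Orc4-only regions, with 7 of 42 (permutation, adjusted p = 0.0033). Near silencing genes lay 3 shared regions, beside ABF1, SIR4 and SIR1 (0.622 expected, permutation p = 0.0402, adjusted p = 0.663). The region at SIR1 came within 1000 bp of that gene only through the peak of Orc1 library 2. The last Orc2 or Orc4 peak of the region ended at 75401, and SIR1 starts at 79261. It is therefore not a place where all 3 subunits were listed beside SIR1. There were 2 shared regions near ORC genes (0.711 expected) and 2 near histone genes (0.595). Replication genes had 4, beside POL1, MCM3, MCM7 and RFA2 (2.26 expected), which were named after their values had been seen. Ribosomal protein genes had 8 (5.34 expected), mating-type genes 1 (0.125) and other genes of high expression 1, beside SSA2 (0.709). The adjusted permutation p was 1 for each of these 6 lists and for glycolysis, rRNA and hexose transporter genes, which had 0 shared regions (1.26, 0.595 and 0.211 expected). The 1 Orc1-only region near an rRNA gene lay beside Tdel_RDN25-1 (0.194 expected, permutation, adjusted p = 1).

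Shared regions were more regularly spaced than random positions. Chromosomes held 19.9 to 22.8 of them per Mb, 21.5 overall. The median gap between neighbouring summits was 48.8 kb, with quartiles of 26.8 and 65.0 kb and a range of 1.45 to 110.5 kb. The coefficient of variation of the 190 gaps was 0.514, against a mean of 0.961 in 2000 sets of random positions, of which the lowest reached 0.768 (permutation over random positions, p = 0.001, the smallest these draws can give).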

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

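The comparison of shared regions near chromosome ends with interior ones, and the tests of fold enrichment and of the lowest −log10 q between the Orc1 libraries, were chosen after the peak lists had been examined. Orc1 differed from Orc2 and Orc4 in how shared regions near the ends compared with those in the interior. The Orc1 minus Orc2/Orc4 difference in log2 peak width had a median of 1.66 at the 16 shared regions within 20 kb of an end and of 0.10 at the 172 regions over 50 kb away, a gap of 1.56 (permutation p = 1e-05, the smallest the resamples can give). For log2 fold enrichment the medians were −0.30 and −1.03, a gap of 0.74 (permutation p = 3e-05). The wide peaks near the ends include those counted in the covered length, so the gap in width is not separate evidence. Fold enrichment is relative to a genomic input for Orc1 and to the mock for the others, so the subunit, the antibody and the control cannot be told apart here.

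Orc1 library 2 covered 2.58 times as much of the terminal 20 kb as library 1 and 1.16 times as much elsewhere. A looser threshold on −log10 q in library 2 was argued against, since its lowest value was 2.002 against 1.92 in library 1, and 0 of its 300 peaks lay below the latter while 7 lay within 0.5 above its own lowest. Stronger enrichment at all bound regions alike stays open: the log2 ratio of fold enrichment, library 2 over library 1, had medians of 0.14 at 22 regions near the ends and 0.13 at 172 interior regions, a gap of 0.006042 (permutation p = 0.926), which does not show that the ratios were equal. The ratio needs a peak in both libraries, so the 49 regions near the ends found in library 2 alone were left out. The comparison could therefore hardly show a difference particular to the ends. Depth, which is unknown, may act in the same way, since a deeper library passes 1 threshold at weaker enrichment. The labels give the libraries different strain numbers and the peak names hold different words (SIR and Kos3V5), so a difference between the strains also stays open as an untested biological explanation.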

How the results depend on the processing

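The alternatives for covered length and glycolysis genes, and 2 subsets for peak width, were chosen after the data had been examined; the others were planned. No result changed direction under any alternative run. Of the alternatives, 135 kept their side of the threshold or stayed within 1.5 times the value, 10 moved further, 9 newly passed the threshold and 3 lost it. For the share of peaks without other subunits the side was fixed in advance, since its exact permutation cannot pass the threshold. Its difference between Orc1 and the others ranged from 5.292 to 16.44 percentage points with a list left out. Shared regions numbered 184 to 213 under all alternatives. The log2 difference in peak width over shared regions, Orc1 minus the others, was 0.2352. It was 0.1683 at regions with exactly 1 peak per list, 0.1417 without Orc1 peaks over 2500 bp and 0.08786 over 50 kb from the ends.

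Orc2/Orc4-only regions numbered 10 and 8 at −log10 q of at least 5 and 10, and 16 to 42 with a list left out. Orc1-only regions numbered 17 to 80 with a list left out. When 1 of the 2 lists sufficed, these classes held 97 and 84. With a list left out, the excess of Orc1-only over shared regions near the ends ranged from 15.49 to 58.25 percentage points. The highest value had Orc1 library 2 as the only Orc1 list, where neighbouring pieces at 1 end counted as separate regions. The excess passed the threshold with summits within 300 bp (22.35 percentage points), reciprocal overlap (18.48), −log10 q of at least 5 (19.3) and windows of 10 kb (17.97) and 30 kb (19.82). It did not at −log10 q of at least 10 (11.14, Fisher's exact p = 0.142) or with equal numbers of peaks (12.63, p = 0.0763). The intergenic share of Orc1-only minus shared regions lost the threshold with reciprocal overlap (−3.261 percentage points), −log10 q of at least 10 (−9.511) and region centres (−0.1188). The cause was not tested in these cases. Gene lists past the threshold numbered 1 to 2 with a list left out, glycolysis genes being added for Orc2/Orc4-only regions without Orc4 library 2 (7 of 42 regions, 0.239 expected, permutation, adjusted p = 0.0033); the adjusted p for tRNA genes was 0.0033 to 0.0066 over the alternatives. The ratio of covered length near the ends was 3.283 to 8.456 with a list left out, and the mean number of glycolysis genes with a peak was 1.25 at −log10 q of at least 10 against 5.75.

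The labels number the libraries of each subunit, but nothing says that a number marks a shared batch. With the replicate block the share of peaks without other subunits differed by 11.47 percentage points (exact permutation p = 0.333, 9 splits), against p = 0.267 without it. Neither design can pass the threshold, so neither speaks to stability. Library 2 had more peaks than library 1 for Orc1 and Orc2 and fewer for Orc4.

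Alternatives on base composition, the origin consensus and short sequence words were not run, since no genome sequence was used here. Depth is unknown, so a peak missing from a list may be below detection there: at 1 of 2 lists the Orc1-only count was 84.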

Other observations

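The tests per library, on glycolysis genes and on gene lengths were chosen after the values had been seen, and those on Orc1-only regions were set before, except that how the weak-origin test was read, the count with rRNA genes and the comparison with shifting were settled after the values had been seen. Genes of glycolysis carried weak Orc2 and Orc4 peaks. In Orc2 library 1, 8 of 11 glycolysis genes lay within 1000 bp of a peak (1.51 after shifting, circular-shift permutation, adjusted p = 0.00165 over 66 tests). The count was 7 in Orc2 library 2 (permutation, adjusted p = 0.00396), 8 in Orc4 library 1 (adjusted p = 0.00293) and 0 in Orc4 library 2 and in both Orc1 lists. The regions lay in PGI1, PGK1, FBA1, TPI1, HXK2, GPM1, TDH2, ENO2 and PFK1, with fold enrichments of 1.67 to 3.09. At −log10 q of at least 10 the mean count over the 4 Orc2 and Orc4 lists fell to 1.25, from 5.75. Ribosomal protein genes showed the same in Orc4 library 1, with 33 of 63 near a peak (8.05 after shifting, permutation, adjusted p = 0.00165), and in Orc2 library 2 with 17 (6.68, adjusted p = 0.0048), and not in Orc2 library 1 (11, adjusted p = 0.443), Orc4 library 2 (7, adjusted p = 0.903) or the Orc1 lists (6 and 7, adjusted p = 1). Genes for tRNAs were near a peak more often than after shifting in all 6 lists, from 65 of 193 in Orc4 library 2 to 103 in Orc4 library 1.

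As explanations of the glycolysis peaks, weak origins beside these genes stay open: the highest of their 3 median fold enrichments, 2.147, lay below the lowest 5th percentile of shared regions in the same lists, 4.03, but so did the median of 2.85 at Orc2/Orc4-only regions in Orc2 library 2, and shared regions exclude weak sites by definition. Recovery of highly transcribed gene bodies that the mock control did not remove also stays open. All 9 regions (100%) had the summit inside a gene, against 10.1% of shared regions (Fisher's exact p = 6.21e-09) and 119 of 215 other regions outside the Orc1 lists and not in all 4 other lists (55.3%, p = 0.0112), but genes fill 79.3% of the genome (exact binomial p = 0.219) and 13 of 35 regions near ribosomal protein genes that were not shared had it there (37.1%; Fisher's exact p against shared regions = 0.000164). Depth could not be weighed. The peaks were absent from Orc4 library 2, so they differed between libraries of 1 subunit.

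For the 17 Orc1-only regions, unspecific recovery at highly expressed genes kept by the genomic input control stays open. Of these regions 0% lay within 1000 bp of a tRNA, ribosomal protein, glycolysis or other gene of high expression (95% interval up to 19.5%). The share was 11.9% after shifting (permutation p = 0.221) and 28.8% for shared regions, which are enriched beside tRNA genes (Fisher's exact p = 0.00761). The class definition favours a low share, since many of these genes had Orc2 or Orc4 peaks. A region with such a peak cannot be Orc1-only. With rRNA genes counted the share of Orc1-only regions was 1 of 17 (up to 28.7%, shifting, permutation p = 0.651, Fisher's exact p = 0.0461), the region beside Tdel_RDN25-1. Weak origins that passed the threshold for Orc1 alone and Orc1 binding near chromosome ends apart from the other subunits cannot be told apart for the class as a whole, and subunit, antibody and control are confounded. Median fold enrichment lay below the lower quartile of shared peaks in both Orc1 lists (3.17 against 5.34 and 4.48 against 5.62), while 23.53% lay within 20 kb of an end against 8.08% (Fisher's exact p = 0.05876). Reads shared between repeated sequences at chromosome ends were not tested, since no genome sequence was used here.

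At 3 places with Orc1 peaks, neighbouring genes had the same lengths of 400 and 1338 bp. They were TDEL0C05820 and TDEL0C05810 beside SLA2 on chromosome 3, TDEL0E00330 and TDEL0E00340 near SIR1 on chromosome 5, and TDEL0G00190 and TDEL0G00200 on chromosome 7, separated by 691, 685 and 685 bp. Shuffled gene lengths gave some pair of lengths at 3 or more places in 218 of 1000 shuffles. That count took any pair of lengths and left out the gaps between the genes and the Orc1 peaks. It therefore cannot tell how often a match in lengths, gaps and Orc1 peaks together would arise. On chromosomes 5 and 7 a tRNA gene of 74 bp also lay before the 400 bp gene, TDEL0Etrna12V at 75008 to 75081 and TDEL0Gtrna5V at 35548 to 35621. No tRNA gene lay between the chromosome 3 pair and SLA2. The shuffles left these tRNA genes out too. Whether the 3 places are copies of the same sequence was not tested. The chromosome 7 place, 34324 to 39641, had Orc1 fold enrichments of 12.1 and 12.5, and 1.64 to 3.0 in the 3 other lists with a peak there.

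Beside the rRNA genes of chromosome 8, both Orc1 lists had 3 peaks, at 784579 to 785132, 791973 to 793865 and 800671 to 802595 in library 1, with 2.27 to 3.0 fold. Orc2 library 2 had 2 peaks of 1.34 and 1.32 fold there, and the other lists had none. Orc2 library 1 had a peak of 3.0 kb over ORC1 (chromosome 4, 164731 to 167729; 4.04 fold), where Orc2 library 2 had 165 bp at 2.17 fold, and a peak of 3.29 kb over RAP1 (chromosome 1, 118596 to 121885; 2.18 fold) listed in no other library. Of the 83 regions in Orc4 library 1 alone, 20 lay near tRNA genes and 19 near ribosomal protein genes, with a median of 2.09 fold.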
